A study of Mus musculus with 2 samples.

How the data were processed

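ATAC-seq was done on midbrain of mouse embryos of strain B6NCrl at day 15.5 of gestation, in 1 group with 2 biological replicates, pools of male and female embryos (78 in replicate 1 and 62 in replicate 2, per the labels). The deposited files were 12 peak lists on build mm10, 6 of the series and 3 for each replicate. Text listings of the file sets were read only for how the lists were derived. The aligner, the peak caller and their versions are not given in the sources used here.

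The signal of a peak is the value the authors' peak caller gave it, deposited without a statement of how the local background was taken. It was compared only within a list. The −log10 p of a peak was likewise deposited as the authors' peak caller gave it. Ranked lists carry a −log10 of the global irreproducible discovery rate (IDR) per the deposited format, and the thresholded lists held only peaks with an IDR of 0.05 or less, which was checked against the ranked lists. The conservative IDR-thresholded list of the series was the main list. Beside it stood each replicate's own IDR-thresholded list, the other IDR-thresholded list of the series, which shared 79744 summits with the conservative list (92.1%), and the replicated and pseudoreplicated lists, whose labels name no IDR threshold. The files hold no counts, so depth per sample is unknown, and intervals cover counting error over regions or genes only.

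Overlapping intervals of a list were merged into regions. Analyses used the 21 chromosomes (19 autosomes, X and Y), and 0 intervals ran past a chromosome end. Transcription start sites (TSSs) were those of protein-coding transcripts of protein-coding genes in GENCODE M21 (21853 genes, 54361 positions). A summit within 1000 bp of a TSS was a promoter summit and others were assigned to exon, intron or intergenic sequence in that order. Regions were shared if they overlapped by at least 50% of the shorter region, and chance was estimated from 20 seeded circular shifts. Shares have 95% exact (Clopper-Pearson) intervals, and a count of 0 was given an upper limit of 3 counts. Values over replicates are means with SD.

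All groups, gene lists, motifs, tests and the alternatives, except those named below, were fixed before the data were examined. There were 20 gene lists, and 1 member, Ahsp, had no match in the annotation. Promoter peaks were compared with all other protein-coding genes by Fisher's exact test, two-sided. Distal summits, over 1000 bp from every TSS, went to the gene of the nearest TSS within 100 kb, and the mean per gene was tested against 100000 random lists drawn within 10 classes of nearest-TSS domain length (permutation test, two-sided, seed 1). For 26 motifs, a window reaching 100 bp to each side of the strongest distal summit of each merged region was compared with a flank 1000 bp away by the exact McNemar test. A flank that fell in a region was moved to the other side, and the pair was dropped if both did. Each consensus was also matched with its letters reversed. The strongest 20% and weakest 20% of distal regions by signal were compared by Fisher's exact test. Adjusted p values follow Benjamini and Hochberg within each family, with a threshold of 0.05. No paired analysis was possible because there was 1 group.

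Genes were named by a fixed rule. In each list these were the 2 members with the highest promoter signal, the 2 with the most distal peaks, and up to 3 in alphabetical order without a promoter peak, or with one for lists of other tissues. The rule also named the 20 genes with the most distal peaks, the 10 regions of highest signal, the 5 widest regions and every motif.

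The alternatives were other peak lists, peaks above the median signal, each replicate's own list, overlaps of 1 bp or of 80% of both regions, the 20000 strongest regions, −log10 p as the ranked value, promoter windows of 500 and 2000 bp, region midpoints, assignment within 50 and 500 kb, unmatched random lists, narrower and wider motif windows, and background windows matched on GC content in bins of 2 points. Merged regions counted once and all distal summits were added after the data had been seen. A count was taken as kept within 1.5 times its main value. A result past its threshold neither in the main setting nor in the alternative was counted as kept, whatever its direction.

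Copies of summit windows were searched with BLAST+ 2.17.0 in the 21 chromosomes and the mitochondrial genome, without unplaced sequence, at 95% identity over 80% of the window, with 300 random regions beside them. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The methods were tested on simulated data. Of simulated regions, 50.55% were recovered as shared where 50% were designed to be. At an unadjusted p under 0.05, the promoter test called 74% of lists of 20 genes with a share of 80% against 50%, and 5% of unchanged lists. The distal test, at the same unadjusted threshold, called 2% of unchanged lists of 20 genes and 51% of lists raised to 2-fold. Its simulated counts were independent between genes and had another mean than the data. These rates are therefore not the power of the reported tests, which used adjusted p. A motif planted in 5% of windows was recovered in 5%, and 0 of 20 unplanted runs were called. Both sets of simulated windows had the same base composition. This test could therefore not show calls that arise from a GC difference between summits and flanks. Families of genes in the closing section were chosen after the results were seen; their symbol patterns were narrowed, and the cytochromes P450 left out, after a first look showed unrelated genes among the matches.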

Results

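Accessible chromatin was profiled in the midbrain of mouse embryos at day 15.5 of gestation by ATAC-seq, in which Tn5 transposase cuts open chromatin and attaches sequencing adapters to it. The data held 1 group with 2 biological replicates. Replicate 1 was a pool of tissue from 78 embryos of both sexes and replicate 2 a pool from 62 embryos. With 1 group there was no comparison between conditions, so the comparisons were between the replicates, between classes of the genome, and between sets of genes and sequence motifs fixed before the data were examined. The deposited files list peaks on the mouse build mm10 and hold no read counts, so the sequencing depth of each replicate is unknown. A peak here is a summit with its interval, and overlapping intervals of a list were merged into regions. The signal of a peak is the authors' own value and was used only to rank or describe peaks within a list.

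The same regions were open in both pools, with the exception of weaker ones. The irreproducible discovery rate (IDR) measures how well peak ranks repeat between 2 sets of peaks. Each replicate's own list was deposited for that replicate alone, so its peaks need not repeat between the 2 pools. At the authors' IDR threshold, replicate 1 had 67596 peaks in 22659 regions. Replicate 2 had 55317 peaks in 18567 regions (mean over both 20613 ± 2894 regions, SD, n = 2). The regions covered 24.5 Mb and 20.2 Mb (mean 22.4 ± 3.02 Mb, SD, n = 2). Of the regions of replicate 2, 92.0% overlapped a region of replicate 1 by at least 50% of the shorter region (95% exact binomial interval 91.6 to 92.4%). Of the regions of replicate 1, 74.9% overlapped a region of replicate 2 (74.3 to 75.5%). Regions shifted along their chromosomes overlapped in 1.14% and 0.933% of cases (means of 20 shifts). Over the 16637 regions paired between the replicates, signal ranks correlated with a Spearman rho of 0.932, which is across regions and not across independent samples.

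Regions found in 1 replicate only were the weak and narrow ones of their own list. In replicate 1 the median signal was 8.44 for shared regions (interquartile range 6.43 to 11.3) and 5.33 for unshared ones (4.59 to 6.2), and in replicate 2 it was 7.90 (5.97 to 10.6) and 5.24 (4.46 to 5.94). The shared region had the higher signal in 84.2% of random pairs in replicate 1 and in 82.9% in replicate 2. Median widths were 1198 bp for shared and 712 bp for unshared regions in replicate 1. In the lowest signal decile of replicate 1, 40.1% of regions had a partner in replicate 2, against 99.96% in the highest decile. Most unshared regions were present in the other replicate's longer list. Of the unshared regions, 91.4% of those of replicate 1 overlapped a region in the pseudoreplicated list of replicate 2, whose label names no IDR threshold (90.6 to 92.1%), as did 94.2% the other way (92.9 to 95.3%). When 80% of both regions had to overlap, the shares fell to 55.4% of replicate 1 and 67.6% of replicate 2.

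**Figure D1:**
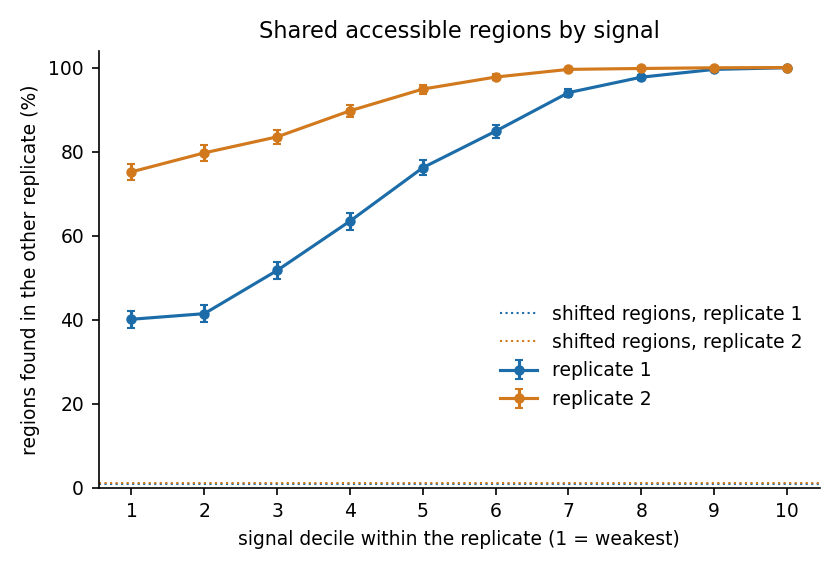
Share of regions with a partner in the other replicate (vertical axis, percent) by signal decile within each replicate (horizontal axis, 1 is weakest), with 95% exact binomial intervals; dotted lines give the share for shifted regions. Replicate 1 rises from 40.1% to 99.96% and replicate 2 starts at 75.2% in the lowest decile.

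The conservative list of the series, which holds peaks repeated between the 2 replicates, had 86587 peaks in 28421 regions over 31.2 Mb of mm10, and it was used for the comparisons below. Promoters dominated it. Of its summits, 50.4% lay within 1000 bp of the transcription start site (TSS) of a protein-coding gene (95% exact binomial interval 50.1 to 50.8%), a class that makes up 2.44% of the sequenced genome, a 20.7-fold excess. Introns held 18.8% of summits (0.546-fold), regions between genes 27.9% (0.464-fold) and exons 2.88% (0.953-fold). In the replicates' own lists the promoter share was 58.4% and 66.5% (mean 62.5 ± 5.75%, SD, n = 2), and the promoter fold was 25.6 ± 2.36. The promoter fold was 12.6 in the replicated list of the series, whose label names no IDR threshold, 29.9 with a window of 500 bp and 11.8 with 2000 bp. Exons changed direction, to 1.22-fold in the replicated list, 1.55-fold with the 500 bp window and 1.01-fold for region midpoints. Promoter regions were also wider, with a median of 1345 bp against 885 bp for regions between genes. They held more summits each, with a mean of 3.58 against 2.52 in introns and 2.68 between genes. Counted by the midpoints of merged regions, the promoter share was 44.0%, so most regions were not at promoters. In the replicated list, 30.6% of summits were at promoters and 35.3% between genes.

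The 10 regions of highest signal were mostly not promoters. Across the whole conservative list, promoter summits had the higher median signal, at 4.16 against 3.76 between genes. Of peaks above the median signal, 55.1% were at promoters. Of the 10 with the highest signal, 8 lay over 1000 bp from every protein-coding TSS, with a median width of 365.5 bp against 862 bp for distal regions in general. The strongest was at chromosome X:143482936-143483180, 35531 bp from the TSS of Pak3, with a signal of 55.03. It was followed by chromosome 2:69355470-69355735, 12987 bp from Abcb11 (50.7), and chromosome 2:3964423-3964690, 53183 bp from Frmd4a (41.8). Regions at 5:60042764-60043133 (38.8), 10:96077546-96077953 (36.7) and 12:97061368-97061856 (28.7) followed, and the summit windows of these last regions also match the mitochondrial genome at 95% identity or more. The region at 4:80002696-80003056 (26.5), nearest to Tyrp1 at 831186 bp, has another near-identical copy in the nuclear genome, and that at 4:88757435-88758104 (26.1) lies 2417 bp from Gm13283. The promoters in this set were those of Depdc1a (3:159494751-159495821, signal 26.2) and Iars, an aminoacyl-tRNA synthetase gene (13:49681385-49682731, 25.5). The widest regions were at the promoters of Ppp2r3d (9:124422581-124426023, 3443 bp, 10 summits), Fzd8, a Wnt receptor gene (18:9211858-9215049, 3192 bp), Tsc22d2 (3:58414230-58417405, 3176 bp) and Spaca6 (17:17825996-17829089, 3094 bp), and at 16:20619695-20622911 (3217 bp, 14 summits), whose strongest summit lay in an intron 1274 bp from the TSS of Camk2n2.

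Fewer regions lay on the sex chromosomes than on the autosomes. Chromosome X had 4.33 regions per Mb in replicate 1 and 3.77 in replicate 2, against 9.16 and 7.49 on the autosomes, a ratio of 0.488 ± 0.0214 (SD, n = 2). Per protein-coding gene, X had 0.747 and 0.650 regions, near the lower end of the autosomes (0.697 to 1.53 in replicate 1 and 0.607 to 1.17 in replicate 2). Chromosome Y had 10 regions in each replicate, or 0.113 per Mb, a ratio of 0.0138 ± 0.00195 to the autosomes. Densities are per Mb of sequenced bases. How much of each chromosome is multi-copy sequence, where reads cannot be placed uniquely, was not taken into account. The libraries pooled embryos of both sexes, in numbers per sex not given in the sources used here.

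Nearly all members of the pan-neuronal, cell cycle and housekeeping lists had a promoter peak, and few receptor genes of the olfactory system and few genes of liver had a promoter peak. Across 21853 protein-coding genes, 12788 (58.5%) had a summit within 1000 bp of a TSS in the conservative list. In a comparison chosen after the results were seen, this share rose with promoter GC. It was 4.12% in the tenth of genes with the lowest GC within 500 bp of the TSS and 92.7% in the highest. The list comparisons below were not matched on GC. The olfactory and vomeronasal receptor genes were among the other genes for every other list. Of 20 gene lists, 5 had more members with a promoter peak than other genes and 7 had fewer, by Fisher's exact test, two-sided, adjusted by the Benjamini-Hochberg method over the lists; genes are not independent replicates. All 20 cell cycle genes and all 20 housekeeping genes had a promoter peak (p = 3.12e-05 and adjusted p = 0.000104 for each list, Fisher's exact test), and in each replicate's own list 95% of the cell cycle genes and 100% of the housekeeping genes did. The highest signals among them were at Mcm3, a subunit of the replicative helicase (20.1), Ccna2, the cyclin A2 gene (17.4), Sdha (14.4) and Rplp0 (14.3). Of 28 pan-neuronal genes, 27 had a promoter peak (96.4%, exact interval 81.7 to 99.9%, p = 8.08e-06, adjusted p = 4.04e-05), and 92.9% did in each replicate's own list. The strongest were at Syt1, a calcium sensor of synaptic vesicles (signal 17.3), and Nrxn1, a synaptic adhesion gene (16.2). The member without one was Neurod2, a neuronal transcription factor with 6 distal peaks.

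Progenitor and signalling genes were above other genes in the conservative list but not in every list. Promoter GC was not matched in this comparison. Members of these lists had a median promoter GC of 61.3% with a promoter peak and 63.3% without, against 54.75% for all genes. In the tenth of all genes with a median GC of 61.0%, 86.3% had a promoter peak, above the share of either list. Of 24 neural progenitor genes, 20 had a promoter peak (83.3%, interval 62.6 to 95.3%, p = 0.0127, adjusted p = 0.0231, Fisher's exact test). The strongest were at Hes6 (8.17) and Gli3, a transcription factor of the hedgehog pathway (7.95). Hes5, Msi1 and Notch1 had none, although Notch1 had 8 distal peaks. In the replicates' own lists the share was 66.7 ± 5.89% (SD, n = 2), and the call was lost in both (exact adjusted p = 0.192 for replicate 1 and 0.444 for replicate 2). Of 26 genes of Shh, Wnt and Fgf signalling, 21 had a promoter peak (80.8%, interval 60.7 to 93.5%, p = 0.0267, exact adjusted p = 0.0445), led by the Fgf-responsive genes Etv5 (14.1) and Dusp6 (11.5). Fgf8, Fgf17 and Fgfr3 had none. That call held in the list of replicate 1 (exact adjusted p = 0.0466) and was lost in that of replicate 2 (adjusted p = 0.361). It was also lost with the 500 bp window (exact adjusted p = 0.119). Among peaks above the median signal both calls were lost (exact adjusted p = 0.144 for signalling and 0.240 for progenitor genes). Both held in the other IDR-thresholded list, in the replicated list and with the 2000 bp window.

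Regional regulators of the midbrain and of the telencephalon were not past the threshold against other genes in the conservative list. Of 30 midbrain patterning genes, 16 had a promoter peak (53.3%, interval 34.3 to 71.7%, adjusted p = 0.675, Fisher's exact test). Pax5, a regulator of the midbrain-hindbrain boundary (11.7), and Pou4f1, a transcription factor of tectal and other neurons (9.17), had the strongest, while Barhl1, Dmbx1 and Gata2 had none. In the replicated list, 27 of the 30 had one (90%, exact adjusted p = 0.00605), 25.5 points above other genes, so this result turned with the list. The 23 telencephalon patterning genes moved likewise, from 13 members (56.5%, exact adjusted p = 0.880) to 21 (91.3%, adjusted p = 0.0122), and they lay below other genes in the list of replicate 2 (26.1%, adjusted p = 0.0149). Arx (8.85) and Lhx2 (8.25) led them, and Bcl11b and Dlx1 also had a promoter peak. Of 15 dopaminergic genes, 9 had one (60.0%, exact adjusted p = 1), with Calb1 (10.2) and Gch1, which makes a cofactor of dopamine synthesis (8.58), the strongest. Aldh1a1, Ddc and Gfra1 had none. In each replicate's own list 33.3% of the dopaminergic genes had one, a difference from other genes of -22.3 points in replicate 1 (exact adjusted p = 0.156) and -20.7 points in replicate 2 (adjusted p = 0.147). Of 16 neurotransmitter identity genes, 6 had one (37.5%, exact adjusted p = 0.193), led by the GABA transporter gene Slc6a1 (7.09) and Gad2, an enzyme of GABA synthesis (4.96). Chat, Dbh and Fev, markers of cholinergic, noradrenergic and serotonergic neurons, had none. In each replicate's own list 18.8% of this list had one, which was below other genes (exact adjusted p = 0.00685 for replicate 1 and 0.00856 for replicate 2), and in the replicated list 62.5% did (adjusted p = 1).

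Among glial and vascular markers the lists were mixed. Of 15 astrocyte lineage genes, 10 had a promoter peak (66.7%, adjusted p = 0.675, Fisher's exact test), led by Glul (11.1) and Nfia (8.75), while Aqp4, Gfap and Gjb6, genes of mature astrocytes, had none. In each replicate's own list 53.3% of this list had one, slightly below other genes (exact adjusted p = 1 for each). Of 15 oligodendrocyte lineage genes, 6 had one (40.0%, exact adjusted p = 0.253), led by Olig1 (9.45) and Ptprz1 (8.03), and Cnp, Cspg4 and Gpr17 had none, although Cnp had one in the list of replicate 1. Of 19 genes of endothelium and pericytes, 8 had one (42.1%, exact adjusted p = 0.237), led by the glucose transporter gene Slc2a1 (7.11) and Kcnj8 (5.95). This list was below other genes in each replicate's own list (21.1%, exact adjusted p = 0.00685 and 0.00856). Of 16 genes of meninges and mesenchyme, 7 had one (43.8%, exact adjusted p = 0.388), led by Lama1 (6.81) and Foxd1 (4.67). Using replicate 2's own list put the oligodendrocyte list at 20% (exact adjusted p = 0.0141) and the meninges list at 25% (adjusted p = 0.0314), both below other genes, and in the replicated list the meninges list was at 68.8% (adjusted p = 0.889). Of 18 microglia genes, 3 had one (16.7%, interval 3.58 to 41.4%, p = 0.000409, exact adjusted p = 0.000910), namely Hexb (7.01), Irf8 (6.16) and C1qc (3.11). Of 16 matched erythroid genes, 2 had one (12.5%, p = 0.000201, exact adjusted p = 0.000502), Gypa (7.85) and Klf1 (1.61). The globin genes of this list include paralogs of similar sequence, whose peaks are less certain. Both calls held in each replicate's own list, at 11.1% and 5.56% of microglia genes and 6.25% of erythroid genes in each, and in the replicated list (27.8% and 25%).

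Most genes of other organs and of other body levels had no promoter peak in the conservative list. Of 39 Hox genes, which pattern the trunk and hindbrain, 1 had a promoter peak (2.56%, interval 0.0649 to 13.5%, p = 6.69e-14, adjusted p = 6.69e-13, Fisher's exact test), Hoxd1 (4.89), and 0 did in either replicate's own list. In the replicated list 8 of the 39 had one (20.5%, exact adjusted p = 2.3e-07). Of 20 liver genes, 1 had one (5.00%, p = 6.58e-07, exact adjusted p = 4.39e-06), Apob (6.69), and 0 did in the list of replicate 2. Of 20 heart and muscle genes, 3 had one (15.0%, p = 0.000104, exact adjusted p = 0.000296), the calcium channel gene Ryr2 (7.59), Nppa (3.47) and Myh7 (2.58), and 7 did in the replicated list (35%, adjusted p = 0.0134). Of 19 pluripotency and germline genes, 4 had one (21.1%, p = 0.00155, exact adjusted p = 0.00311), among them Dazl (9.63), Klf4 (7.56) and Esrrb (5.14), and 15.8% and 10.5% did in the replicates' own lists. Of 1463 olfactory and vomeronasal receptor genes, 4 had one (0.273%, interval 0.0745 to 0.699%, against 62.7% of other genes), with Vmn1r4 (12), Olfr658 (9.02), Olfr94 (8.75) and Olfr452 (5.70).

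**Figure D2:**
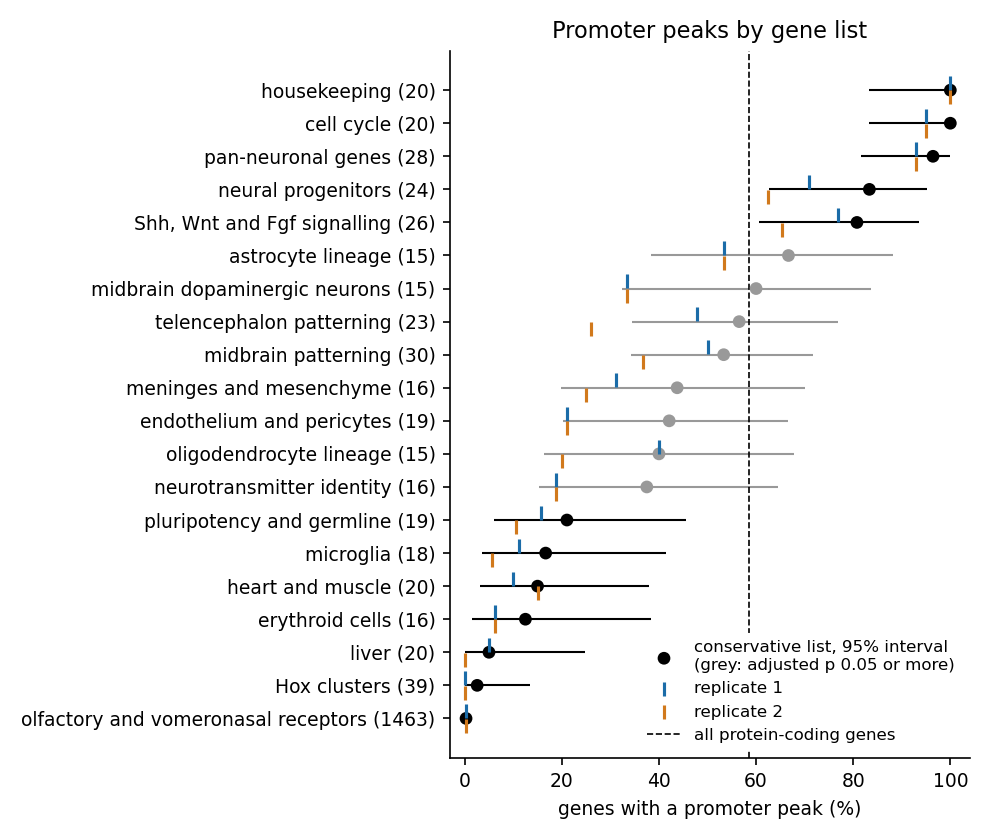
Share of the genes of each list with a promoter peak (horizontal axis, percent) in the conservative list with 95% exact binomial intervals, and in each replicate's own list; list sizes are in brackets and the dashed line is the share of all protein-coding genes, 58.5%. Cell cycle and housekeeping genes lie at 100% and the receptor genes at 0.273%.

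Distal peaks gathered around progenitor, signalling and pan-neuronal genes, and in the astrocyte list mainly at Nfib and Nfia. Of 42934 summits over 1000 bp from every TSS, 31837 were within 100 kb of one and were assigned to the nearest gene. These counts are of summits, and 1 merged region can hold several. Counted as merged regions by their strongest summit, Ascl1 had 7 for its 20 summits, En1 6 for 17 and Nfib 11 for 31. The mean number per gene of each list was compared with 100000 random lists matched on the length of the genes' nearest-TSS domains (permutation test, two-sided, Benjamini-Hochberg over the 20 lists). Of the lists, 5 were above their matched lists and 1 was below. The 24 neural progenitor genes had a mean of 6.83 distal peaks and a median of 5.5, 2.60-fold the matched mean of 2.63 (permutation p = 0.0002, adjusted p = 0.002), and the ratio in the replicates' own lists was 2.58 ± 0.0309 (SD, n = 2). Ascl1, a proneural transcription factor, had 20 distal peaks, the strongest at 10:87446872-87448238 between genes, and Zbtb20 had 17. The 15 astrocyte lineage genes had 6.07 per gene, 2.63-fold the matched mean (permutation p = 0.00294, adjusted p = 0.0118, replicates 2.84 ± 0.140), but only 8 of the 15 had any, and of the 91 peaks most were at the gliogenic factor genes Nfib (31 peaks, the strongest in its intron at 4:82512732-82513828) and Nfia (20). The 26 Shh, Wnt and Fgf signalling genes had 5.85 per gene, 2.16-fold (permutation p = 0.0012, adjusted p = 0.006, replicates 2.77 ± 0.123), with 17 each at Gli2 and Wnt7b. In the lists of replicates 1 and 2, Gli2 had 7 and 1 and Wnt7b 15 and 13. The 28 pan-neuronal genes had 6.57 per gene, 2.11-fold (permutation p = 0.0009, adjusted p = 0.006, replicates 2.22 ± 0.168), with 25 at Nrxn1 and 21 at Myt1l, a neuronal transcription factor.

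The 30 midbrain patterning genes had 4.90 distal peaks per gene, 1.74-fold their matched mean of 2.82 (permutation p = 0.0139, adjusted p = 0.0465), and 28 of them had at least 1. En1, a homeobox gene of the midbrain and midbrain-hindbrain boundary, had 17, the strongest at 1:120643891-120645065 between genes, 41606 bp from its TSS, and Meis2 had 11. In the lists of replicates 1 and 2, En1 had 8 and 3 and Meis2 11 and 2. The ratio of the midbrain patterning list was 1.5 ± 0.0581 in the replicates' own lists (SD, n = 2), where the call was lost (permutation adjusted p = 0.310 for replicate 1 and 0.362 for replicate 2). It was also lost in the other IDR-thresholded list (1.54-fold, permutation adjusted p = 0.147), among peaks above the median signal (1.62-fold, adjusted p = 0.0861) and with assignment up to 500 kb (1.54-fold, adjusted p = 0.121). It held in the replicated list (1.84-fold, permutation adjusted p = 0.00304), with assignment within 50 kb (2.08-fold, adjusted p = 0.0109) and with merged regions counted once (1.97-fold, adjusted p = 0.0045). The 15 dopaminergic genes had 1.00 per gene, 0.409-fold (permutation adjusted p = 0.175), with 6 at Kcnj6 and 4 at Ret. The 23 telencephalon genes had 2.61 per gene, 0.997-fold (permutation adjusted p = 0.967), with 8 at Dlx2 and 6 at Bcl11b, and a ratio of 1.10 in the list of replicate 1 and 0.694 in that of replicate 2. Without matching on domain length the ratios of the 5 lists above were larger, from 3.36 for midbrain patterning to 4.68 for neural progenitors.

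The other lists did not pass, except for the receptor genes. Neurotransmitter identity genes had a ratio of 1.78 (permutation adjusted p = 0.175), with 21 peaks at Slc6a1 and 9 at Slc6a5. Slc6a1 had 6 and 1 in the lists of replicates 1 and 2, and Slc6a5 had 3 in each. Oligodendrocyte genes had a ratio of 2.18 (permutation adjusted p = 0.121), with 14 at Ptprz1 and 7 at Mbp, and passed in the other IDR-thresholded list (2.90, adjusted p = 0.0143) and in the replicated list (2.25, adjusted p = 0.0332). The neurotransmitter list passed in the replicated list (1.93, permutation adjusted p = 0.0373). Housekeeping genes had a ratio of 2.00 and cell cycle genes 1.93 (permutation adjusted p = 0.200 and 0.175), with 15 peaks at Ywhaz and 7 each at Ccne1 and Rrm2. Ccne1 had 6 in each replicate's own list, while Rrm2 had 0 in that of replicate 1 and 3 in that of replicate 2. Ratios were 1.38 for heart and muscle (8 at Acta1), 1.21 for microglia (8 at Spi1, 7 at Ptprc), 1.12 for liver (9 at Ttr, 6 at Pck1), 0.852 for meninges and mesenchyme (9 at Foxc1), 0.774 for pluripotency and germline (6 at Nanog), 0.690 for endothelium and pericytes (8 at Sox17, 5 at Cdh5) and 0.396 for erythroid genes, all with permutation adjusted p of 0.565 or more. Counted as merged regions, Foxc1 had 4, Acta1, Spi1, Ptprc, Ttr, Sox17 and Cdh5 had 2 each, and Pck1 and Nanog had 1 each. In the lists of replicates 1 and 2 the ratio turned to 0.650 and 0.674 for microglia, fell to 0.410 and 0.398 for meninges and mesenchyme, and was 0 and 0.202 for erythroid genes and 1.24 and 1.45 for cell cycle genes (permutation adjusted p of 0.310 or more). Within 50 kb the ratio was 1.35 for meninges and 1.20 for housekeeping genes, and that of liver was 0.732 in the replicated list (permutation adjusted p of 0.593 or more). Hox genes had 3 distal peaks in all, a ratio of 0.181 (permutation adjusted p = 0.123), and passed as below their matched lists in the other IDR-thresholded list (0.0594, adjusted p = 0.0333) and without matching (0.0528, adjusted p = 0.00016). Receptor genes had 0.142 per gene, 0.198-fold (permutation p = 2e-05, the smallest that the permutations can give, adjusted p = 0.0004), and 0.0976-fold without matching.

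**Figure D3:**
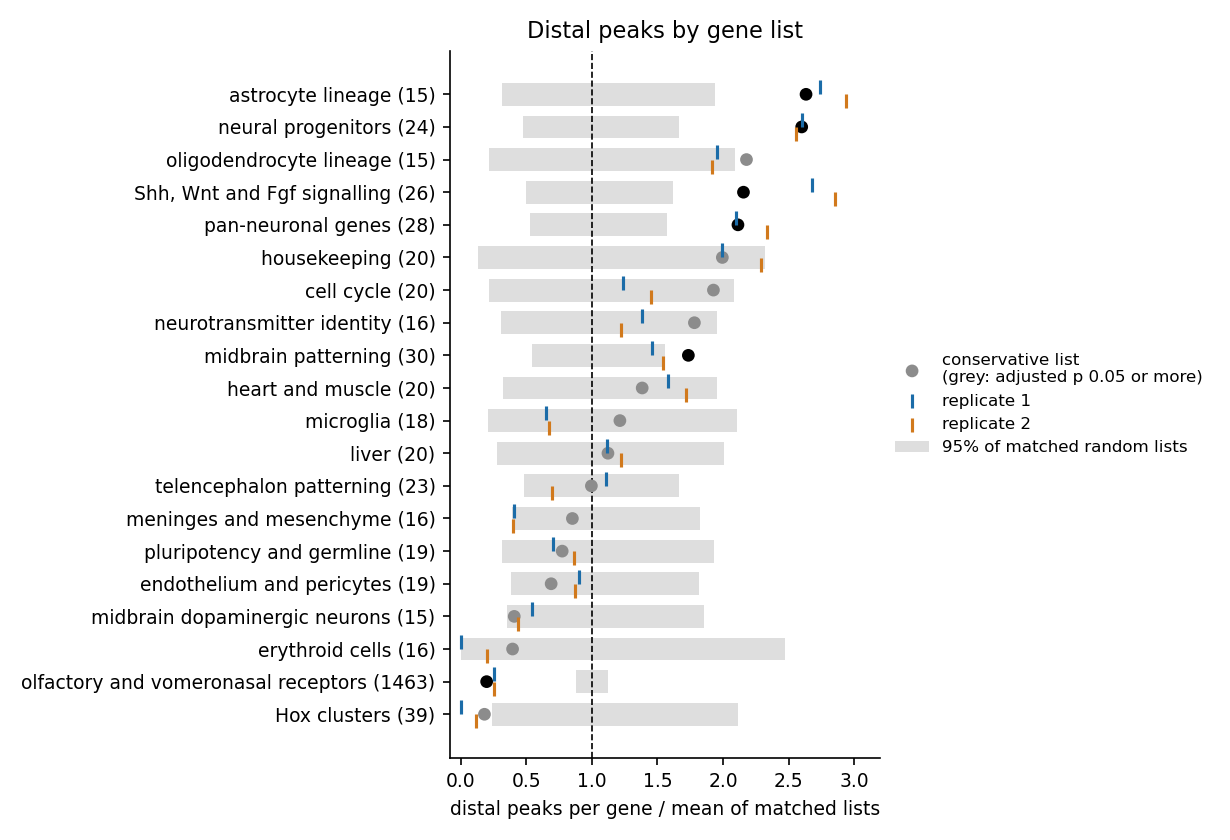
Mean number of distal peaks per gene of each list divided by the mean of its matched random lists (horizontal axis), in the conservative list (points) and each replicate's own list (ticks); grey bars hold 95% of the matched random lists. Astrocyte lineage (2.63) and neural progenitor genes (2.60) are highest among the lists, and the receptor genes lie at 0.198.

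The 20 genes with the most distal peaks had 24 to 52 each, without matching on domain length. Maml3, a coactivator of Notch signalling, had 52 distal peaks in 16 regions. The lists of replicates 1 and 2, counted separately, gave it 32 and 19. Its strongest was in an intron at 3:52007256-52008215 (signal 8.09). Cstad had 44, Pde4d, a cAMP phosphodiesterase gene, had 35, and Ank3, which encodes the axon initial segment protein ankyrin-G, and Ncor2, a corepressor, had 33 each. Counted as merged regions, Cstad and Pde4d had 10 each and Ank3 and Ncor2 9 each. Ncor2 had 17 and 5 peaks in the lists of replicates 1 and 2. Usp29 had 32, Nfib 31, Mef2c, a neuronal transcription factor, 30, Ripor2 28, and Chd7, a chromatin remodeller, Frmd4a and Myo3b 27 each. Gse1 had 26, Adcyap1r1, Cxxc5, Fyn, Gdf6, Nrxn1 and Sertad2 had 25 each, and Ccser1 had 24. Ccser1 had 9 in the list of replicate 1 and 0 in that of replicate 2. Myo3b was the only gene of these 20 without a promoter peak. The highest distal signal among them was at Frmd4a (2:3964423-3964690, 41.8), the narrow region named above, followed by Pde4d (13:109440285-109441828, intron, 15.3), Nfib (12.2), Sertad2 (11:20561151-20562352, intron, 11.9) and Chd7 (4:8647008-8648553, between genes, 11.9).

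Distal summits carried motifs of CTCF, RFX, NFI, ZIC, MEIS and POU factors and E-boxes more often than sequence beside them. The motifs of OTX, GATA and AP-1 were less frequent than in sequence beside them, but not than in genome windows of the same GC content. In 16906 distal regions, a window reaching 100 bp to each side of the strongest distal summit was paired with a window of equal width 1000 bp away and outside any region. Of 26 motifs, 15 were more frequent at summits and 3 less frequent, by the exact McNemar test, two-sided, with Benjamini-Hochberg adjustment; regions are not independent replicates. CTCF, the insulator-binding protein (consensus CCASYAGRKGGC), matched 6.80% of summit windows and 0.106% of flanks (63.8-fold), with 6.27 ± 0.0850% in the replicates' lists (SD, n = 2). Its fold was 67.4 in the list of replicate 1 and 37.9 in that of replicate 2, where 0.164% of flanks matched, and ranged from 21.4 over all distal summits to 96.8 with a narrower window of 50 bp to each side. RFX, a family of ciliogenic factors (GTTGCYNNGGCAAC), matched 141 windows (0.834%) and 0 flanks, and 1.05 ± 0.0997% in the replicates' lists (exact adjusted p = 3.73e-42). NFI (TGGCNNNNNGCCA) matched 1.60% against 0.467% (exact adjusted p = 2.30e-25). The E-box CAGCTG of basic helix-loop-helix factors matched 19.6% against 9.04% (exact adjusted p = 3.27e-171) and the proneural E-box CAGATGG 6.66% against 4.45% (exact adjusted p = 3.36e-18). ZIC (CAGCAGG) matched 12.3% against 5.13%, MEIS (CTGTCA) 18.3% against 13.4%, the POU octamer (ATGCAAAT) 2.35% against 1.18% and POU4 (TGCATAAT) 1.23% against 0.532%, with exact adjusted p of 9.12e-12 or less. Each of these was also above its flanks in both replicates' lists, although the fold of POU4 was 1.52 in that of replicate 2 against 2.31 in the conservative list. Against random genome windows of the same GC content, each stayed above background, but some by less. The fold of CTCF fell from 63.8 to 39.7, that of CAGCTG from 2.17 to 1.49 (background 13.2%) and that of ZIC from 2.40 to 1.48 (background 8.33%).

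Motifs of general promoter factors were also more frequent at distal summits, with NFY (RRCCAATSRS) at 3.38% against 1.21%, SP/KLF (GGGGCGGGG) at 2.83% against 0.633%, ETS (CCGGAAGT) at 0.544% against 0.154%, NRF1 (GCGCATGCGC) at 0.195% against 0.0118% and YY1 (AAGATGGCGGC) at 0.0592% against 0.00591% (exact adjusted p of 0.0179 or less). The summit shares of all of these motifs were higher in each replicate's own list. ETS matched 0.658% of windows in the list of replicate 1 and 0.935% in that of replicate 2, and YY1 0.0855% and 0.101%. Against the GC-matched windows the fold of SP/KLF fell from 4.47 to 1.82 (background 1.55%), that of NRF1 from 16.5 to 4.12 and that of ETS from 3.54 to 2.38. In the replicated list the folds of NRF1, ETS and NFY were 6.11, 1.5 and 1.76. Distal means far from TSSs of protein-coding transcripts, so promoters of other transcripts count as distal. Of the conservative list, 17028 regions held a distal summit, and in 15959 the strongest summit was distal. Some windows thus lie in regions whose strongest summit is at a promoter. The part of such promoters in these motifs was not tested. The YY1 call was lost with matched genome windows (2.5-fold against 10-fold over flanks, exact adjusted p = 0.246), with the narrower window (4 windows against 0, 0.203) and among peaks above the median signal (8 windows against 1, 0.0635). MEF2 (CTAWWWATAG) matched 0.402% against 0.254% (exact adjusted p = 0.0305), a call lost in both replicates' lists (0.0679 and 0.108), in the other IDR-thresholded list (0.322), among peaks above the median signal (0.211), with the narrower window (0.606) and over all distal summits (0.390). Its odds were 1.60 in the conservative list, 1.67 and 1.76 in the replicates' lists, which hold fewer windows, and 1.28, 1.38, 1.26 and 1.13 in the other 4 settings. Against GC-matched windows its fold rose from 1.58 to 6.18 (background 0.0648%). Summit windows had more G and C than flanks, with medians of 52.2% and 44.8%. Against random genome windows of the same GC content, the motifs that lay below flanks no longer did. GATA (AGATAAG, 1.92% against 2.74% in flanks) was at 1.93% against 1.94% (exact adjusted p = 1), AP-1 (TGASTCA, 3.27% against 3.86%) was at 3.27% against 3.17% (0.736), and OTX (TAATCC, 6.71% against 7.60%) turned to 6.71% against 5.71% (0.000209). The AP-1 call against flanks was also lost in both replicates' lists (exact adjusted p = 0.421 and 0.103), in the other IDR-thresholded list (0.276), among peaks above the median signal (0.145), with the narrower window (0.667) and over all distal summits (0.353), with odds of 0.840 in the conservative list and 0.928, 0.846, 0.922, 0.894, 1.06 and 0.959 in these settings, and AP-1 was above flanks in the replicated list (exact adjusted p = 0.0478). The LIM homeodomain motif (YTAATTAR), at 1.94% and 1.86% of summits and flanks (exact adjusted p = 0.627), was above the matched windows (0.760%, 5.56e-21), and above flanks in the replicated list (0.000629) and with a wider window of 200 bp to each side (3.62e-05). SOX (CCATTGTT), EBF (TCCCNNGGGA), TEAD (RCATTCCW), PU.1 (AGAGGAAGTG), REST (CAGCACCNNGGACAG) and HNF4 (CAAAGTCCA) did not pass, and HNF1 (GTTAATNATTAAC) matched 0 windows, which allows a share of up to 0.0177%. Of these, EBF and TEAD were above flanks in the replicated list (exact adjusted p = 2.44e-08 and 0.00315), as was REST (0.0153), and HNF4 was below them there (0.00145) and in the list of replicate 2 (0.0220). EBF was also above flanks over all distal summits (odds 1.56, exact adjusted p = 6.24e-06) and with the wider window (odds 1.25, 0.0446), and was not above the GC-matched windows (0.524% against 0.689%, 0.0862). With the letters of each consensus reversed, the summit to flank odds of CAGCTG fell from 2.48 to 1.47 and those of ZIC from 2.66 to 1.76. SP/KLF reads the same reversed and has no such control.

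**Figure D4:**
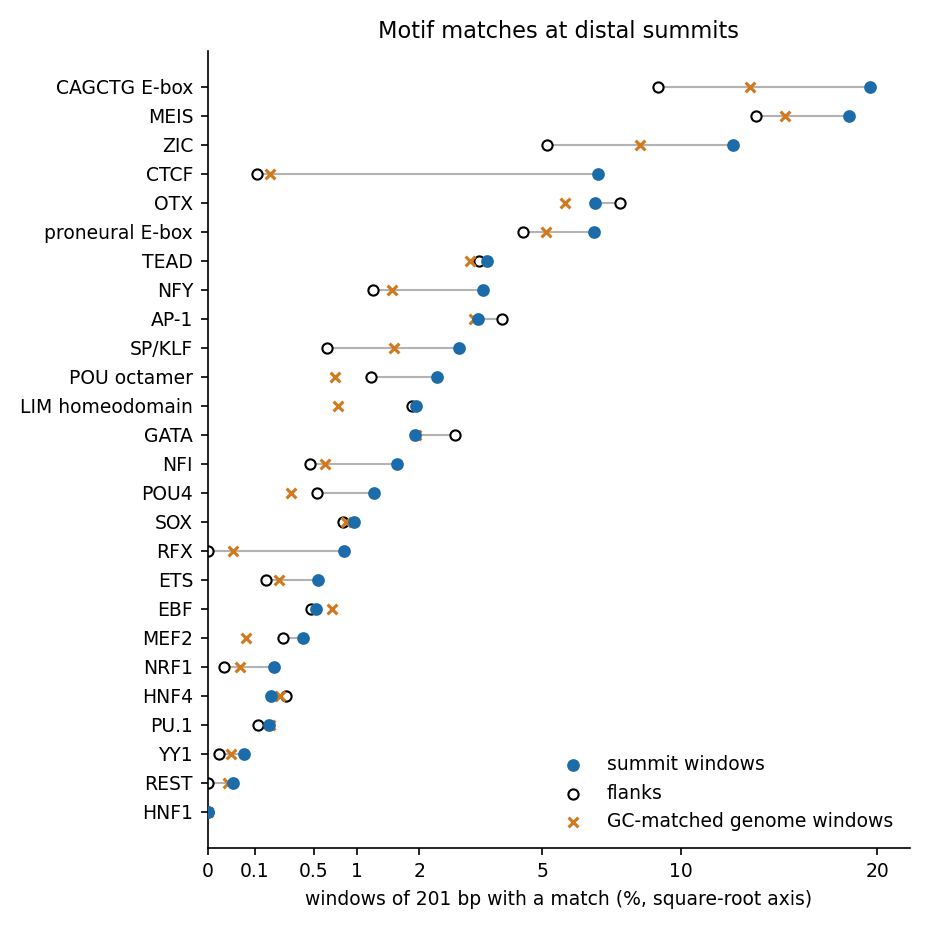
Share of windows, reaching 100 bp to each side of the position, with a match to each motif (horizontal axis, percent on a square-root scale) at 16906 distal summits, in paired flanks and in GC-matched genome windows. CTCF lies at 6.80% against 0.106% in flanks, and OTX lies between the flanks (7.60%) and the GC-matched windows (5.71%).

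Strong distal regions carried 5 of the 26 motifs more often than weak ones, with the lowest p for NFY. The strongest 20% of distal regions by signal (3405 regions, signal 7.14 or more) were compared with the weakest 20% (3405 regions, 3.97 or less) by Fisher's exact test, two-sided, over the 26 motifs. NFY, a factor that binds CCAAT boxes, matched 7.08% of strong and 2.06% of weak regions (odds 3.63, exact adjusted p = 1.06e-22). The shares were 8.76% and 2.55% in the list of replicate 1 and 10.3% and 3.02% in that of replicate 2. Distal regions include promoters of noncoding transcripts and distal summits beside promoter summits, whose part in this result was not tested. CTCF matched 7.22% and 4.58% (exact adjusted p = 5.68e-05) and ETS 1.26% and 0.470% (adjusted p = 0.00288), and both passed in each replicate's list. The odds of CTCF were 1.62 in the conservative list, 1.60 in that of replicate 1 and 2.54 in that of replicate 2. Those of ETS were 2.71, 2.88 and 2.79 in the same order. RFX (1.23% and 0.382%, exact adjusted p = 0.000694) and CAGCTG (21.2% and 17.0%, adjusted p = 8.96e-05) passed in the conservative list and were lost in the lists of replicate 1 (0.118 for each) and replicate 2 (0.121 and 0.152). The odds of RFX were 3.26 in the conservative list, 2.16 and 2.88 in the replicates' lists, which had 2351 and 1590 regions on each side, and 3.95 in the other IDR-thresholded list, where those of NFY were 3.74. The odds of CAGCTG were 1.32, and 1.18 and 1.22 in the replicates' lists. No other motif passed, except MEF2 with the narrower window, which was lower in strong regions (0.0294% and 0.323%, exact adjusted p = 0.0328). Strong and weak regions had median GC contents of 52.2% and 54.2%, and the same 5 motifs passed when they were matched on it.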

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

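The tests of this part were written before their outcomes were seen.

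Peaks that pass the IDR threshold in the ranked list that holds every peak of the conservative list, but are missing from the latter, carry signal that the comparisons above do not use. There were 238 such summits in 89 regions, of which 148 summits in 56 regions lay on the main chromosomes. The other ranked list of the series, which holds every peak of the other IDR-thresholded list, had 229 passing summits missing from that list. The widest of the 89 regions was chromosome 1:24611587-24616170 of mm10 (4584 bp, 14 summits, signal 3.49). It aligned to the mitochondrial genome over 100% of its length, at 99.96% identity, so reads of mitochondrial DNA could account for this region. Other removed regions were narrow, with 1 summit and high signal, such as 9:24541942-24542230 (45.2) and 6:103648978-103649356 (40.8). Among summit windows of the 56 regions, 41.07% (exact interval 28.1 to 55.02%) had another near-identical copy, against 1% of 300 random regions (0.207 to 2.89%). Multi-copy sequence may thus explain part of the removed peaks, but the share lies under the 50% set in advance and unplaced sequence was not searched, which keeps it open for the whole set. No biological explanation was tested, since the design has 1 group.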

How the results depend on the processing

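Merged regions counted once and all distal summits were added after the data were seen; the other alternatives were planned. Over all results and alternatives, 687 values kept their direction and side of the threshold, lay within their spread, or were past the threshold in neither setting (some of these changed direction), 43 moved, 25 newly passed, 30 no longer passed and 9 reversed. Unless said otherwise, the cause was not tested.

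The share of replicate 1 regions found in replicate 2 was 55.4% when 80% of both regions had to overlap, 70.1% in the pseudoreplicated lists and 79.5% for the 20000 strongest regions, and for replicate 2 it was 67.6%, 80.8% and 86.4%. Spearman's rho was 0.893 in the pseudoreplicated lists and 0.952 for −log10 p, by which shared regions were higher in 92.2% of pairs.

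The promoter fold was 12.6 in the replicated list, 18.1 for region midpoints, 29.9 with a 500 bp window, 11.8 with 2000 bp and 23.95 to 27.29 with 1 replicate left out. Exons reversed to 1.22 (replicated list), 1.01 (midpoints) and 1.55 (500 bp), and were at 0.707 above the median signal, 0.811 with 2000 bp and 0.721 to 0.782 with 1 replicate left out. Introns were at 0.884 (replicated list), 0.458 (above the median signal), 0.624 (midpoints), 0.704 (500 bp) and 0.336 to 0.433 (1 replicate left out), and intergenic sequence at 0.587 (replicated list), 0.522 (midpoints), 0.520 (500 bp) and 0.328 to 0.405 (1 replicate left out). A 500 bp window moves summits from the promoter class into the others by construction. The X ratio was 0.350 in the pseudoreplicated lists and 0.511 above the median signal, and the Y ratio 0.00901 and 0.0105.

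Lists with more promoter peaks numbered 3 above the median signal and 3 to 4 with 1 replicate left out, where 9 to 12 lists had fewer. In the replicated list, midbrain patterning genes reversed to 25.5 points above other genes and telencephalon genes to 26.8 points. Neural progenitors fell short of the threshold above the median signal (14.4 points) and with 1 replicate left out (8.51 to 15.2), and signalling genes above the median signal (16.7), with 500 bp (19.07) and without replicate 1 (11.4 to 21.3 over both). Neurotransmitter genes newly passed, at -33.5 points in the other IDR-thresholded list, -31.45 above the median signal and -36.9 to -35.3 with 1 replicate left out. With 1 replicate left out, telencephalon genes were at -27.9 to -7.84 points, oligodendrocyte genes at -34.0 to -15.7, endothelial genes at -34.6 to -33.0 and meningeal genes at -29.0 to -24.4.

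For distal peaks, 2 lists were below their random lists in the other IDR-thresholded list and 2 without matching, where Hox genes passed (0.0594 and 0.0528). Midbrain patterning genes fell short in the other IDR-thresholded list (1.54), above the median signal (1.62), with 500 kb (1.54) and with 1 replicate left out (1.46 to 1.54). Neurotransmitter genes passed in the replicated list (1.93) and oligodendrocyte genes in the other IDR-thresholded list (2.90) and the replicated list (2.25).

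Against GC-matched windows 0 motifs were below background, and OTX reversed to 1.002 points above it. AP-1 reversed to 0.226 points in the replicated list, 0.0944 with the narrower window and 0.1002 against GC-matched windows. Between strong and weak regions, 3 motifs were higher with either replicate left out (3 to 3), and 1 was lower with the narrower window. Depth limits these results to an unknown degree, since read counts were not analysed here.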

Other observations

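The gene families, the test of the IDR threshold and the comparisons of promoter GC over all genes and over the 9 genes below had no outcome written in advance and count as chosen after the results were seen; the other tests were written before their outcomes were seen.

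Families of neuronal surface proteins differed in promoter peaks in the conservative list (Fisher's exact test, two-sided, Benjamini-Hochberg over 12 families). The families were not matched with the other genes on promoter GC. Of 57 clustered protocadherin genes, which give neurons individual surface identities, 4 had a promoter peak (7.02%, exact adjusted p = 7.54e-16), namely Pcdhac1, Pcdhac2, Pcdhgc3 and Pcdhgc4, and 4 members had one in each replicate's own list. Ephrins and Eph receptors, which guide axons, had one in 20 of 22 genes (90.9%, exact adjusted p = 0.00410; 16 and 15 in the replicates' lists), and semaphorins and plexins in 25 of 29 (86.2%, exact adjusted p = 0.00413; 24 and 23). GABA-A receptor subunits had one in 11 of 12 genes (91.7%, exact adjusted p = 0.0288; 11 and 11) and voltage-gated potassium channels in 19 of 22 (86.4%, exact adjusted p = 0.0140; 16 and 16). Ionotropic glutamate receptor subunits had one in 13 of 16 (81.2%, exact adjusted p = 0.103), which did not pass. Zinc-finger genes named Zfp had one in 337 of 394 (85.5%, exact adjusted p = 8.23e-31; 331 and 325). Sox factors (11 of 19), forkhead factors (26 of 44) and cadherins (14 of 23) were near the other genes (exact adjusted p = 1 for each). Keratins and their associated proteins had one in 1 of 110 genes, Krt10 (0.909%, exact adjusted p = 1.18e-39; 0 and 1), and beta-defensins in 0 of 42 (exact adjusted p = 3.37e-16).

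The 8 distal regions among the 10 of highest signal were narrow and lay far above the distal median signal of 5.34. Of these, 100% had a −log10 p above the median of distal regions (39.5), the lowest being 360.9, which argues against few reads. The 8 were picked by signal, a score from the same peak caller. No other regions of high signal were compared for −log10 p, which limits this test. All 8 were found in each replicate's own list, which argues against a signal of 1 library for these regions. This does not set them apart, since the list holds repeated peaks. Of the other 1588 distal regions in the tenth of highest signal, 96.3% were also found in both replicates. Another near-identical copy in the genome may account for part of the 8 regions. Of their summit windows, 50% (4 of 8, exact interval 15.7 to 84.3%) had one, against 2.67% of 300 random distal regions (1.16 to 5.19%). Of the 8, 3 matched the mitochondrial genome. The 4 without a copy, which include the regions near Pak3, Abcb11 and Frmd4a, stay unexplained. Narrow regions of high signal were also among the removed peaks described above. No biological explanation was tested.

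Of 50 progenitor and signalling genes, 9 lacked a promoter peak in the conservative list (Hes5, Msi1, Notch1, Nr2e1, Fgf8, Fgf17, Fgfr3, Wnt3a and Wnt5a, named after their values were seen). The IDR threshold may account for part of this, since 6 of the 9 had one in the replicated list and Wnt3a, Fgf8 and Fgf17 did not. GC content of the promoter cannot be told apart: in gene families used in nearly all cells, the share with a promoter peak differed by -1.15 points between the highest and the middle GC class (98.9% and 100%, Fisher's exact p = 1), where the measure is near its upper limit. Over all genes, which differ in more than GC, the share was 91.0% in the highest (exact interval 90.1 to 91.8%) and 66.1% in the middle class. The 9 had a median GC of 63.3% against 61.3% in members with a peak, and 4 of the 9 lay below the latter. High GC was thus not common to the 9 and did not go with fewer peaks over all genes, but without a matched comparison GC stays open. No biological explanation was tested.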
